A study of Mus musculus with 6 samples.

How the data were processed

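Aorta RNA of mice on a high fat diet or on regular chow was measured on 6 Affymetrix mouse arrays, 3 per diet. Per the labels' protocols, RNA of 3 aortas was pooled for each array and 5 µg of RNA entered the synthesis of labelled cRNA. The deposited values are signal intensities on a linear scale, 1 per probe set and array. MAS5, which combines the perfect match and mismatch probes of a probe set into 1 signal, was named in the submitters' processing notes, and its version and settings are not given in the sources used here. The 2% trimmed mean over all probe sets was 150.05 on each of the 6 arrays, so the deposited scaling was kept. No detection calls were used here, so that low signals could not be separated from background: 42.0% to 46.3% of the signals on an array lay under 50. The ratio of the 3' to the 5' control probe set lay between 0.89 and 1.38 for Gapdh and between 1.27 and 1.94 for actin.

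The table held 22690 probe sets, of which 64 controls were left out. Genes were named from the platform annotation. Of 22626 probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none, and none was named from a probe set with several. By gene ID, 20364 of the former matched a current gene table, used for names alone, and 0 symbols changed. Probe sets with the suffix _x_at or _s_at, which can bind transcripts of related genes, numbered 2981, and Idh3a and Cyp2b10 are named from such probe sets, as is the Fdft1 probe set of smallest p.

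Signals were transformed as log2(signal + 6), with the pseudocount at the 10th percentile of all signals. A fold change is on that scale and understates the change of low genes. Probe sets with a mean log2 value above the 40th percentile, a signal of 40.7, were kept, which left 13575. The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, in each direction, up to 10 genes past the threshold whose diets did not overlap, by fold change, with 1 probe set per gene, leaving out clone-like symbols. It was filled up to 10 with the genes of smallest unadjusted p, given as values. For each list it took up to 4 members past the threshold adjusted over the list alone, or otherwise the 2 of smallest p. Lipe, Ucp1 and members named beyond these were chosen after their values were seen.

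The 30 gene lists held 743 entries, of which 668 were on the array. For each gene the probe set of highest mean was used, which gave 8327 genes, 543 of them in a list. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 30 lists. Camera with a correlation estimated from the data and fry were run beside it. Fry's directional test asks whether the genes of a list move, on balance, one way, and its mixed test whether they change in either direction. With 3 pools against 3, an exact permutation test of a list mean cannot give a p below 0.1.

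The same steps were tested on simulated data of 13575 probe sets in 20 runs with 200 changed probe sets. A log2 change of 1 was recovered in 78% and one of 1.5 in 97% of cases, 0 calls had the wrong sign, and 6.36% of the calls were false. With the preset correlation, lists without a change were called 0.1 times per run, and a planted shift of 0.5 was called in 20 of 20 runs. What an estimated correlation or fry would have called was not scored. Simulated genes were independent, so that these runs do not cover lists whose genes vary together. Noise was normal with the variances after eBayes, and with 200 planted changes the adjustment is less strict than where few pass. The shares recovered can therefore overstate what the real arrays allow: Kng1 and Atoh8, with log2 fold changes of 1.77 and -1.51, did not pass.

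The alternatives were pseudocounts of 1 and 21, no filter and a filter at the 60th percentile, quantile normalization, equal medians, no variance trend, a robust variance model, array weights, the replicate number as a block, each array left out in turn, 1 probe set per gene and the mean of all probe sets of a gene. A cardiac marker covariate, the fit without the pair of arrays lowest in cardiac markers, and the counts adjusted over a list alone in each setting were added after seeing the data. A tricarboxylic acid cycle list and a cytochrome P450 family 2 list were also chosen after seeing the data. Each was first run with the genes that prompted it, and then, once those results had been seen, without them. Both versions are reported. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for the tables and figures.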

Results

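RNA of the mouse aorta was profiled on 6 Affymetrix arrays, 3 from mice on a high fat diet and 3 from mice on regular chow. Each array carried RNA pooled from 3 aortas that had been freed of adventitia and periaortic fat, and the pools were described as independent, so n = 3 pools per diet throughout. The mice were C57BL/6J, an inbred strain that becomes obese on a high fat diet, and were males where the label stated the sex, which it did not for high fat replicate 1. The diet lasted 16 to 18 weeks. It began at 10 weeks of age in high fat replicates 2 and 3, and chow replicates 2 and 3 were 26 to 28 weeks old. The label of high fat replicate 1 gave an age of 16 to 20 weeks, which leaves little time before a diet of 16 to 18 weeks, so that it is unclear whether this was the age at collection. That of chow replicate 1 gave no age, and a difference in age between the diets cannot be ruled out from the labels. Median signals lay between 58.4 and 66.6 on the 6 arrays. The mean correlation of an array with the other 5, across probe sets, was lowest for high fat replicate 2 at 0.953 and at most 0.965 for the rest. The number of arrays limits the precision of every value, and p-values measure the spread between pools, not between animals.

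The comparison of the diets asked which genes of the aorta differed in expression after a high fat diet. Fabp3, which encodes a fatty acid binding protein of oxidative tissues, rose from a signal of 669 ± 102 on chow to 2140 ± 269 on high fat diet (SD, n = 3 each), a log2 fold change of 1.67 ± 0.15 (SE, adjusted p = 0.00163, limma). Npr3, which encodes the clearance receptor for natriuretic peptides, rose from 73.4 ± 4.5 to 267.5 ± 34.6, a log2 fold change of 1.78 ± 0.17 (adjusted p = 0.00163). Idh3a, a catalytic subunit of the mitochondrial isocitrate dehydrogenase, rose from 271.7 ± 20.0 to 531.9 ± 30.9, a log2 fold change of 0.96 ± 0.14 (adjusted p = 0.0435). Cyp2e1, a cytochrome P450 that oxidises ethanol and other small molecules, fell from 1438 ± 93.3 to 391.9 ± 109.1, a log2 fold change of -1.90 ± 0.19 (adjusted p = 0.00299). Car3, a carbonic anhydrase abundant in adipocytes and muscle, and Retn, the adipocyte hormone resistin, fell as well.

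Of 13575 probe sets tested, 10 passed an adjusted p of 0.05, 5 higher and 5 lower on high fat diet. All 3 arrays of one diet lay above all 3 of the other for each gene named among them, which the naming rule required. Car3 fell from 2205 ± 442 to 822 ± 220, a log2 fold change of -1.43 ± 0.20 (adjusted p = 0.0435). A second Car3 probe set, at 2216 against 4135, had a log2 fold change of -0.91 and did not pass (adjusted p = 0.0768). Retn fell from 464 ± 70.7 to 216.9 ± 1.3, a log2 fold change of -1.07 ± 0.16 (adjusted p = 0.0435). Tra2b, which encodes a splicing regulator, fell from 641.7 ± 73.0 to 279.5 ± 31.1, a log2 fold change of -1.18 ± 0.15 (adjusted p = 0.0223), and its second probe set had -0.46 without passing. The other Idh3a probe sets had log2 fold changes of 0.94 and 0.60 and did not pass. A pair of probe sets had no gene in the annotation used. In this pair, 1 fell from 3330 ± 351 to 763 ± 173 and 1 rose from 92.7 ± 17.3 to 424.4 ± 76.8 (adjusted p = 0.00163 each). The remaining probe set, higher on high fat diet, belonged to a clone-named gene that the naming rule only counts.

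At an adjusted p of 0.10, 14 probe sets passed, 8 higher and 6 lower. At an unadjusted p of 0.05 there were 954, 532 higher and 422 lower, where chance gives 679 and another division of the same 6 arrays into 3 and 3 gave 923. The arrays of the diets did not overlap for 1676 probe sets, 12.35% of those tested, and chance gives 10%. Fabp3, Npr3, Cyp2e1 and both probe sets without a gene passed in each of 18 other settings, leaving out single arrays included. Idh3a passed in 7, Retn in 8, Car3 in 10 and Tra2b in 11 of them. The count of 10 became 5 without high fat replicate 2, 5 without chow replicate 2, 6 without high fat replicate 3 and 16 without high fat replicate 1.

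**Figure D1:**
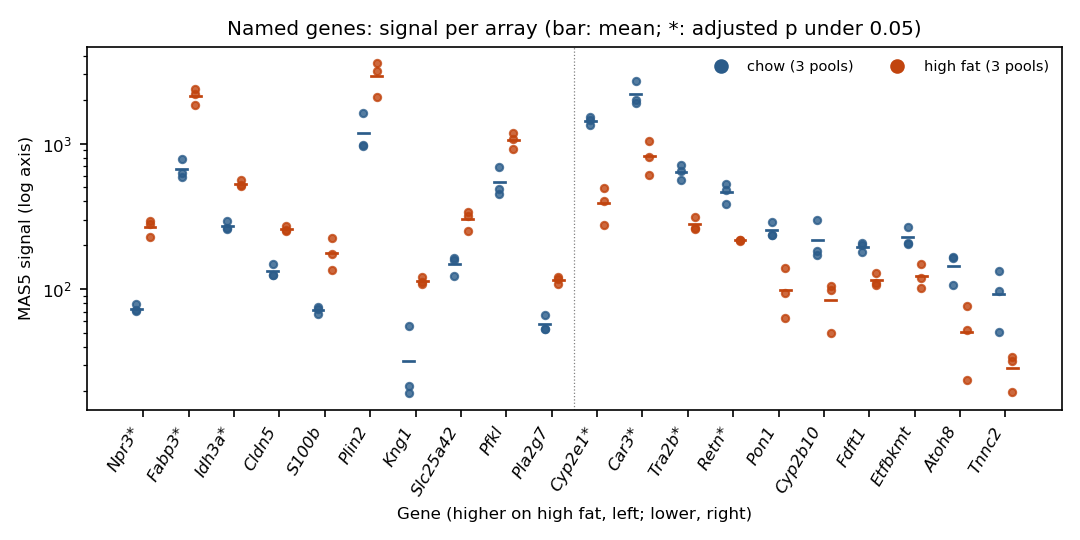
MAS5 signal (log axis) of the 20 named genes on each of the 6 arrays, with chow pools in blue, high fat pools in orange and a bar at each group's mean. Asterisks mark genes with an adjusted p under 0.05, among them Fabp3, with means of 669 on chow and 2140 on high fat diet, and Cyp2e1, with means of 1438 and 391.9.

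Other genes with small unadjusted p-values did not pass the adjustment and are given as values. Among those with higher means on high fat diet, Plin2, which coats lipid droplets, had 2935 ± 750 against 1184 ± 376 (log2 fold change 1.32, adjusted p = 0.148). Cldn5, a tight junction protein of endothelium, had 257.9 ± 11.4 against 132.2 ± 13.5 (0.94, adjusted p = 0.0873), and S100b, a calcium-binding protein of Schwann cells and some adipocytes, had 177.7 ± 43.8 against 71.9 ± 4.2 (1.21, adjusted p = 0.0905). Kng1, Slc25a42, Pfkl and Pla2g7 had log2 fold changes of 1.77, 1.0, 0.98 and 0.95, with adjusted p-values of 0.150, 0.150, 0.160 and 0.205. Among those with lower means, Pon1, an esterase carried on high density lipoprotein, had 98.8 ± 38.7 against 253.1 ± 32.4 (-1.37, adjusted p = 0.156). Cyp2b10 had 84.6 ± 30.0 against 216.2 ± 70.2 (-1.31, adjusted p = 0.305), and its other probe sets had -1.19 and -1.07. Fdft1, the squalene synthase of cholesterol synthesis, had a log2 fold change of -0.73 (adjusted p = 0.306), while its other probe sets had -0.73 and 0.64. Etfbkmt, Atoh8 and Tnnc2 had log2 fold changes of -0.85, -1.51 and -1.45, with adjusted p-values of 0.310, 0.319 and 0.330.

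Among 30 gene lists fixed beforehand, genes of fatty acid oxidation and PPAR targets had the smallest p with the preset correlation, while brown adipocyte markers, described next, had the smaller p with an estimated correlation and by fry. All 23 measured members had higher means on high fat diet, with a median log2 fold change of 0.51 (camera adjusted p = 1.19e-19 with the preset correlation, adjusted p = 0.616 with an estimated correlation). Adjusted over the list alone, 16 rose and 7 did not pass, and over all probe sets 1 rose, Fabp3. Besides Fabp3 and Plin2, the members of smallest p were Cpt2, a carnitine palmitoyltransferase of the inner mitochondrial membrane, at 675.1 ± 80.3 against 393.7 ± 71.7, and Etfa, an electron carrier of fatty acid oxidation, at 1671 ± 203 against 1074 ± 180. The count of 16 became 9 without high fat replicate 2 and 9 without chow replicate 2, and 11 without the variance trend. Oxidative phosphorylation genes, the subunits of the respiratory chain and ATP synthase, had higher means for 46 of 48 members, with a median of 0.21 (adjusted p = 1.49e-09, adjusted p = 0.668 with an estimated correlation). None of the 48 passed adjusted over the list alone in limma, and 10 had an unadjusted p under 0.05, while 3 passed with quantile normalization. Uqcrc1, at 2269 ± 423 against 1511 ± 188, and Ndufb9, at 2603 ± 110 against 1926 ± 185, had the smallest p. Without high fat replicate 2 the median was 0.14.

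Markers of brown adipocytes moved with these lists. Of 12 measured, 10 had higher means on high fat diet, with a median of 0.50 (adjusted p = 8.86e-10, adjusted p = 0.616 with an estimated correlation), and 7 rose and 5 did not pass adjusted over the list alone, against 1 over all probe sets. Fabp3, described above as a gene of oxidative tissues, belongs to this list too, so not every member is particular to brown adipocytes. The list mean correlated with that of the cardiac muscle markers, described below, at 0.56 across the 6 arrays. Ppara, a transcription factor of fatty acid oxidation, had 210 ± 5.4 against 110.1 ± 26.7, Cox7a1 had 944.2 ± 89.5 against 519.8 ± 140.7 and Elovl3 had 628.5 ± 148.5 against 337.2 ± 66.5. Ucp1, the uncoupling protein made by brown adipocytes and chosen here after its values were seen, had a signal of 2479 ± 317 on chow and 3480 ± 283 on high fat diet, a log2 fold change of 0.49 ± 0.13 (adjusted p = 0.445 over all probe sets). White adipocyte markers went both ways and the list did not pass (19 members, median 0.15, adjusted p = 0.129), although with the preset correlation it passed without chow replicate 3 (median 0.22, adjusted p = 0.00125). On all arrays it had adjusted p = 0.672 with an estimated correlation, which was not run without that array. Adjusted over the list alone, 3 of them rose, Cd36, Gpd1 and Lipe, 2 fell, Retn and Car3, and 14 did not pass, while Retn was the member past the threshold over all probe sets. Gpd1, at 3172 ± 436 against 1859 ± 643, makes glycerol phosphate.

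Cardiac muscle markers differed more between pools of one diet than between diets. All 13 had higher means on high fat diet, with a median of 0.69 (adjusted p = 0.00235, adjusted p = 0.672 with an estimated correlation), and none passed adjusted over the list alone in limma or had an unadjusted p under 0.05. Ryr2, the calcium release channel of heart muscle, had 201 ± 41.0 against 149.2 ± 26.4, and Nppa, the precursor of atrial natriuretic peptide, had 55 ± 23.1 against 32.5 ± 4.7. The mean of the list, as a log2 deviation from the mean of the 6 arrays, was -1.20, 1.29 and 0.95 in high fat replicates 1, 2 and 3 and -0.15, 0.31 and -1.21 in chow replicates 1, 2 and 3. The list did not pass without high fat replicate 2 (median 0.25), high fat replicate 3 (0.39) or chow replicate 3 (0.13), and without high fat replicate 1 its median was 1.44 and 12 of the 13 passed adjusted over the list alone. With this cardiac mean as a covariate, an alternative chosen after seeing the data, the fatty acid oxidation list had a median of 0.51, the brown adipocyte list 0.51 and the oxidative phosphorylation list 0.18, each past the threshold with the preset correlation. Without the covariate these lists had adjusted p = 0.616, adjusted p = 0.616 and adjusted p = 0.668 with an estimated correlation, which was not run with the covariate. With it, 12 of the 23 fatty acid oxidation genes passed adjusted over the list alone.

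**Figure D2:**
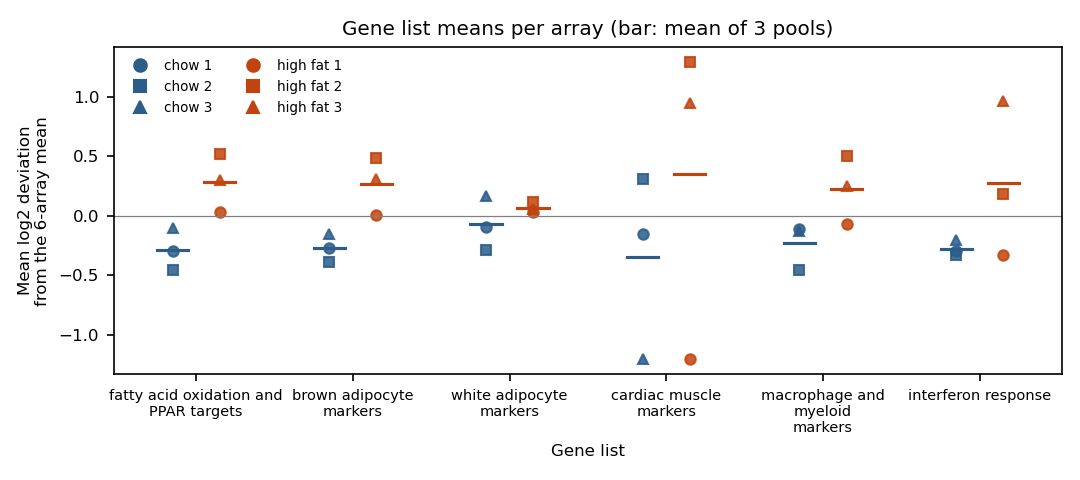
Mean of each of 6 gene lists on each array, as a log2 deviation from the mean of the 6 arrays, with chow pools in blue, high fat pools in orange and a marker shape for each replicate number. The cardiac list spans -1.21 to 1.29 and its diets overlap, whereas the fatty acid oxidation list spans 0.03 to 0.52 on high fat diet and -0.45 to -0.10 on chow.

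Macrophage and myeloid markers had higher means for 23 of 24 members on high fat diet, with a median of 0.50 (adjusted p = 6.07e-10, adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 7 rose and 17 did not pass, and none passed over all probe sets in limma, where 12 had an unadjusted p under 0.05. Cd36, a scavenger receptor and fatty acid transporter that adipocytes also express, had 1554 ± 255 against 852 ± 218. Fcer1g, an Fc receptor subunit, had 117.4 ± 37.4 against 48.6 ± 13.2, Lgals3, galectin 3, had 370.7 ± 119.7 against 181.8 ± 14.2, and Adgre1, the F4/80 antigen, had 228.4 ± 67.1 against 128.6 ± 5.8. The 7 became 0 without high fat replicate 2 and 0 without chow replicate 2, 2 without high fat replicate 3, 13 without high fat replicate 1, and 3 with the cardiac covariate. The median was 0.31 without high fat replicate 2.

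Interferon response genes had higher means for 21 of 24 members, with a median of 0.52 (adjusted p = 2.01e-07, adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, Irf7, a transcription factor of the type I interferon response, was the member that rose, at 239.4 ± 131.2 against 76.9 ± 15, and the other 23 did not pass. This count of 1 became 0 without high fat replicate 2, high fat replicate 3 or any 1 of the chow replicates, and 0 without a filter, without the variance trend, with the robust variance model and with the cardiac covariate. With the cardiac covariate the list median was 0.33. The list mean was 0.97 in high fat replicate 3, 0.18 in high fat replicate 2, -0.33 in high fat replicate 1 and between -0.33 and -0.20 on chow. Without high fat replicate 3 the median was 0.16 and the list did not pass (adjusted p = 0.179), and without high fat replicate 1 the median was 0.87 and 14 members passed adjusted over the list alone.

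Endothelial markers had a median of 0.16, with 20 of 25 higher (adjusted p = 0.00857, adjusted p = 0.668 with an estimated correlation), and Cldn5 alone rose adjusted over the list alone. Without high fat replicate 1 the list did not pass (adjusted p = 0.0931), and without high fat replicate 3 the members past the threshold adjusted over the list alone numbered 2. Smooth muscle contractile genes had a median of -0.10, with 17 of 20 lower (adjusted p = 0.0195, adjusted p = 0.668 with an estimated correlation), and none passed adjusted over the list alone in limma, where 1 had an unadjusted p under 0.05. Itga8 had 1554 ± 309 against 1952 ± 76.4 and Actg2 had 554.2 ± 117.7 against 713.1 ± 97.9. The list did not pass without high fat replicate 2 (median -0.09) or chow replicate 2 (-0.05), and the median was -0.17 without chow replicate 1. Heat shock genes and chaperones had a median of -0.13, with 18 of 20 lower (adjusted p = 0.0213, adjusted p = 0.668 with an estimated correlation), and none had an unadjusted p under 0.05 in limma. Hspe1 had 726.5 ± 41.2 against 867.9 ± 91.7 and Hsp90aa1 had 1227 ± 193 against 1475 ± 233. The list did not pass without high fat replicate 3 (-0.06), chow replicate 2 (-0.09) or chow replicate 3 (-0.09), and the median was -0.21 without high fat replicate 1. Without chow replicate 1, 1 member passed adjusted over the list alone.

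Genes of fatty acid synthesis and desaturation had a median of 0.13, with 13 of 17 higher (adjusted p = 0.0321, adjusted p = 0.672 with an estimated correlation). None passed adjusted over the list alone in limma, and 4 had an unadjusted p under 0.05. Me1, malic enzyme, had 1043 ± 320 against 618.4 ± 134.1 and Scd2, a stearoyl-CoA desaturase, had 636.8 ± 64.4 against 456.2 ± 75.1. The list did not pass without high fat replicate 2 (median 0.10), high fat replicate 3 (0.14), chow replicate 1 (0.04) or chow replicate 2 (0.06), and without chow replicate 3 its median was 0.30 and 7 members passed adjusted over the list alone. Without high fat replicate 1, 1 member did. Nerve and Schwann cell markers had a median of 0.01, with 6 of 9 higher (adjusted p = 0.0321, adjusted p = 0.668 with an estimated correlation). S100b and Sncg, the latter also made by adipocytes, rose adjusted over the list alone, and Sncg had 270.8 ± 34.0 against 163.4 ± 21.4. The list did not pass without high fat replicate 1 (median -0.03), high fat replicate 2 (0.10), chow replicate 2 (0.03) or chow replicate 3 (0.07), and the median was 0.20 without high fat replicate 3 and 0.07 without chow replicate 1.

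The other lists did not pass on all 6 arrays. Of the sterol lists, cholesterol synthesis and uptake (adjusted p = 0.499) held Hmgcs1, which rose from 589.5 ± 83.0 to 982.5 ± 197.9, and a probe set of Fdft1, which fell from 276.9 ± 36.1 to 166.9 ± 39.2, both adjusted over the list alone. Cholesterol efflux and LXR targets (adjusted p = 0.331) held Abcg1, a sterol transporter that rose from 72.2 ± 2.2 to 118.1 ± 9.6, and Apoc1, an apolipoprotein that fell from 704.6 ± 98.3 to 394.4 ± 125.0, again adjusted over the list alone. Among antioxidant genes and NRF2 targets (adjusted p = 0.539), the metallothioneins Mt1 and Mt2 fell and Sod2 and Gsta4 rose adjusted over the list alone, with log2 fold changes of -0.57, -0.85, 0.58 and 1.03. The median of this list was -0.03 and its mean 0.01. Per2 of the circadian clock list (adjusted p = 0.249) fell from 179.6 ± 13.4 to 111.2 ± 15 and Alas2 of the red cell list (adjusted p = 0.185) fell from 407.1 ± 259.8 to 156.5 ± 69.8, adjusted over the list alone. The red cell list had 3 measured members of 15. Its mean was 0.89 in chow replicate 3, against -0.05 and -0.07 in chow replicates 1 and 2. Tnnc2, Pvalb and Atp2a1 of the skeletal muscle list (adjusted p = 0.249) fell adjusted over the list alone, with log2 fold changes of -1.45, -1.21 and -0.73. The median of that list was 0.02 and its mean -0.09. Vasoactive and renin-angiotensin genes (adjusted p = 0.608) held Npr3, which rose, and 20 members that did not pass.

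No member passed adjusted over the list alone in the remaining lists. Their adjusted p-values in camera were 0.0942 for the unfolded protein response, 0.190 for class II antigen presentation, 0.331 for lymphocyte markers, 0.339 for collagens and elastic matrix, 0.383 for adhesion molecules, chemokines and cytokines, and 0.714 for matrix proteases and inhibitors. They were 0.539 for the cell cycle, insulin and growth factor signalling, calcification and osteochondrogenic genes, and fibroblast and adventitia markers, and 0.699 for immediate early genes. Over all probe sets, the list members past the threshold, by the probe set used for each gene, were Fabp3, Npr3 and Retn. With the preset correlation, leaving out single arrays brought some of these lists past the threshold, and an estimated correlation was not run in these settings: the unfolded protein response without high fat replicate 2 (adjusted p = 0.0457) or chow replicate 2 (0.0220), class II antigen presentation without chow replicate 1 (0.0414) or chow replicate 3 (0.0368), and collagens without chow replicate 1 (0.0488). The same held for red cell markers without chow replicate 1 (0.0399) or chow replicate 2 (0.0433) and for skeletal muscle markers without high fat replicate 2 (0.0431) or chow replicate 3 (0.0368). The red cell list, with 3 measured members, was highest in chow replicate 3, which both of its fits kept. In all, 11 of the 30 lists passed with the preset correlation, 9 higher and 2 lower. With an estimated correlation 0 passed, by fry's directional test 0 and by its mixed test 11 passed, of which 4 were among the 11 of camera. Another division of the same 6 arrays into 3 and 3 gave 13 lists with the preset correlation. Among the 11 lists, the exact permutation test gave p = 0.1, its lowest possible value, for fatty acid oxidation, macrophage, brown adipocyte and endothelial genes. Its p was 0.2 for oxidative phosphorylation and nerve markers and 0.3 for the interferon response and heat shock genes. For smooth muscle genes and fatty acid synthesis it was 0.4, and for cardiac markers 0.5.

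**Figure D3:**
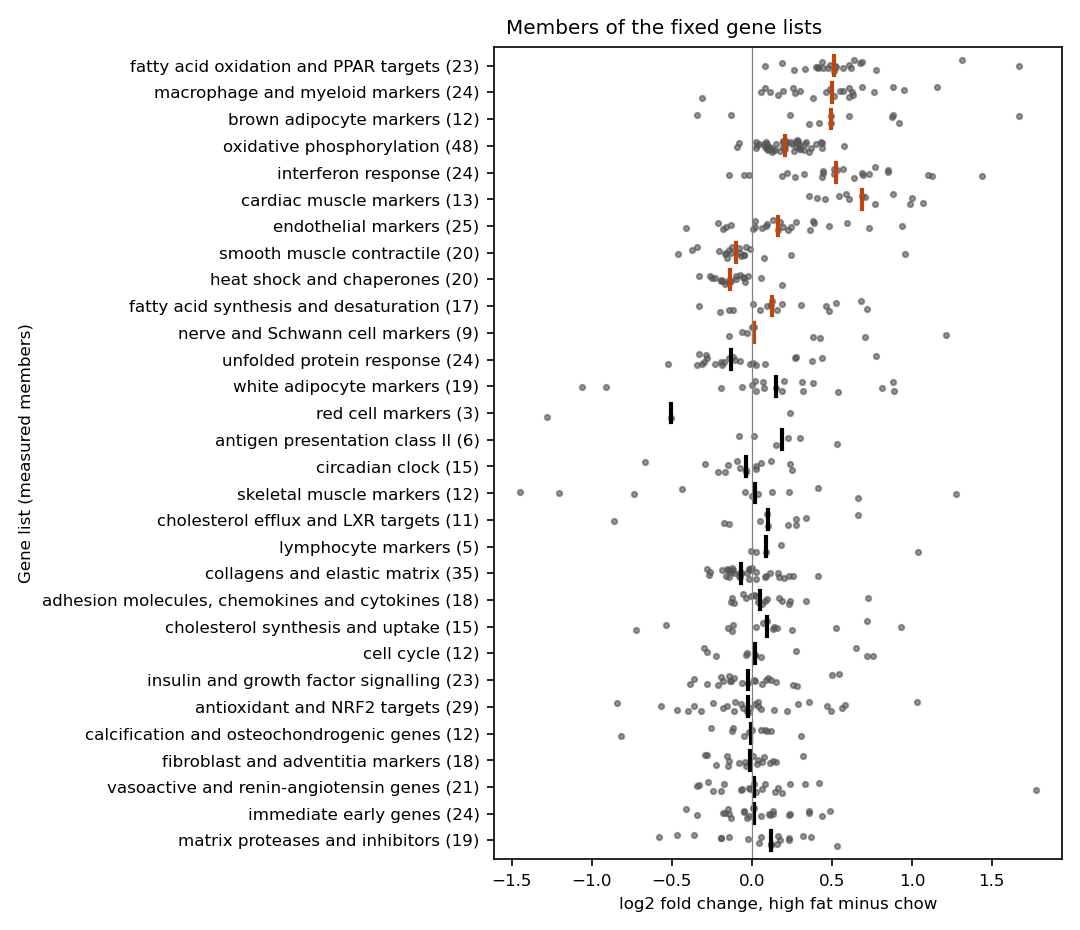
Log2 fold change (high fat minus chow) of every measured member of the 30 gene lists, a point per gene, with a vertical bar at the list's median, orange where the list had an adjusted p under 0.05 with the preset correlation and black otherwise. Medians reach 0.69 for cardiac muscle markers and 0.51 for fatty acid oxidation genes, and the median of the smooth muscle contractile genes is -0.10.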

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

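The cardiac covariate and the fit without high fat replicate 1 and chow replicate 3, the arrays lowest in cardiac markers, were chosen after seeing the data, and the other settings before. All 10 probe sets kept their direction in 18 settings. The count of 10 (5 higher, 5 lower) became 6 without a filter (3 higher, 3 lower), 5 without the variance trend (3 and 2), 6 with the cardiac covariate (3 and 3), 45 without the cardiac-low arrays (32 and 13) and 6 with 1 probe set per gene, where fewer were tested (3 and 3). Of the 45, 8 were among the 10. Leaving out single arrays gave 5 to 16, with 3 to 10 higher and 2 to 7 lower. The replicate numbers did not pair the pools: the deviations of same-numbered pools correlated at 0.034, 0.171 and -0.111, and not every pool correlated best with its own number. With the replicate block 5 probe sets passed (3 higher, 2 lower), all among the 10, and 5 interferon response genes rose adjusted over the list alone, against 1 without it. The lists past the threshold, 11, numbered 7 without high fat replicate 3 and 13 without chow replicate 1, the range when single arrays were left out. They numbered 0 with an estimated correlation, 0 by fry's directional test and 11 by its mixed test, 4 of them among the former. Under the estimated correlation and the directional test the medians stay the same by construction and no list passed: 0.512 for fatty acid oxidation (fry adjusted p = 0.343), 0.501 for macrophage markers (0.432), 0.495 for brown adipocyte markers (0.312), 0.205 for oxidative phosphorylation (0.432), 0.523 for the interferon response (0.601), 0.688 for cardiac markers (0.630), 0.162 for endothelial markers (0.432), -0.101 for smooth muscle genes (0.432), -0.134 for heat shock genes (0.601), 0.126 for fatty acid synthesis (0.630) and 0.011 for nerve markers (0.432).

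With preset camera, the fatty acid oxidation, macrophage, brown adipocyte and oxidative phosphorylation lists passed in 19 of 19 settings. All 19 kept the preset correlation of 0.01, while the correlations estimated on all arrays were 0.52, 0.45, 0.22 and 0.33, with which none passed. The smallest unadjusted p of camera with an estimated correlation was 0.0209, for brown adipocyte markers. Whether that test could find a real shift with so few arrays was not simulated, so its lack of passing lists does not show that no list changed. The robust variance model does not enter camera, so that setting repeats the main list test. With the cardiac covariate the cardiac list reversed to -0.124, by construction, and smooth muscle genes (-0.070) and heat shock genes (-0.096) did not pass. Without the cardiac-low arrays, endothelial markers (0.161), smooth muscle genes (-0.123) and nerve markers (0.010) did not pass. Smooth muscle genes did not pass with quantile normalization (-0.063). With the mean of all probe sets of a gene, smooth muscle genes (-0.056), heat shock genes (-0.146), fatty acid synthesis (0.159) and nerve markers (0.085) did not pass. Fatty acid synthesis did not pass without the variance trend (0.126) or with array weights (0.089), nor nerve markers with the stricter filter (0.001). When single arrays were left out, medians spanned 0.164 (without high fat replicate 3) to 0.872 for the interferon response, 0.131 (without chow replicate 3) to 1.437 for cardiac markers, 0.121 to 0.242 for endothelial markers, -0.168 to -0.049 (without chow replicate 2) for smooth muscle genes, -0.208 to -0.055 (without high fat replicate 3) for heat shock genes, 0.042 (without chow replicate 1) to 0.295 for fatty acid synthesis and -0.025 (without high fat replicate 1) to 0.201 for nerve markers. Lists that did not pass in the comparison itself passed in some settings: the unfolded protein response in 5, skeletal muscle markers in 4, white adipocyte markers and class II antigen presentation in 3 each, red cell markers in 2, and the circadian clock and collagens in 1 each. Without a filter these included white adipocyte markers (0.168) and skeletal muscle markers (-0.244). Without the cardiac-low arrays, the members passing adjusted over the list alone numbered 21 for fatty acid oxidation, 13 for macrophage markers, 12 for the interferon response, 11 for cardiac markers, 7 for fatty acid synthesis and 3 for oxidative phosphorylation. Except where a construction is named, the cause was not tested. Signals near background limit what can be said of low genes.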

Other observations

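The tests below were chosen after the results they bear on had been seen, except the count over other splits of the arrays, which was set beforehand. Idh3a prompted a list of tricarboxylic acid cycle genes, the mitochondrial cycle that oxidises acetyl-CoA. The list also held genes of enzymes that feed the cycle, Pdha1, Pdhb and Dlat of pyruvate dehydrogenase and Pcx, pyruvate carboxylase. Pcx was the member with a lower mean. Run first with Idh3a and the succinate dehydrogenase genes, 19 of 20 had higher means on high fat diet (median 0.35, camera adjusted p = 7.49e-08, adjusted p = 0.594 with an estimated correlation). Those genes had prompted the list or sat in another one, so it was run again without them once the first result had been seen, and 14 of 15 had higher means (median 0.36, adjusted p = 7.38e-06, adjusted p = 0.648 with an estimated correlation). Suclg1 had 1073 ± 169 against 761.2 ± 25.7 and Dlst had 821.2 ± 64.4 against 613.9 ± 86.7. None of the 20 passed adjusted over the list alone in limma (smallest 0.0602).

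Cyp2e1 and Cyp2b10 prompted a list of cytochrome P450 family 2 genes, enzymes that oxidise drugs, steroids and fatty acids. Run first with both, 8 of 11 had lower means (median -0.14, adjusted p = 0.0133, adjusted p = 0.594 with an estimated correlation). Without both, run after that result had been seen, 6 of 9 had lower means and the list did not pass (median -0.10, adjusted p = 0.535). The first result therefore rested on the genes that had prompted it, and Cyp2f2, at 166.4 ± 128.4 against 182.8 ± 36.4, and the other 8 did not pass adjusted over the list alone.

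The number of probe sets past the threshold was 10 for the diets and at most 1 in the other splits of the 6 arrays, so 1 of the 10 splits gave as many. The number of lists was 11 for the diets and at most 13 in the other splits, so 4 of the 10 splits gave as many. With 10 splits a share under 0.05 cannot be reached.

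The higher means of fatty acid oxidation genes may reflect more brown fat left on the high fat pools, since Ucp1 had a signal of 2479 even on chow. This stays open, as the mean log2 change of the 23 list members differed from that of Ucp1, Cidea and Cox8b by 0.03 ± 0.12 (SE). For more adipose tissue of any kind, 9 genes of all adipocytes changed less than the list, by -0.38 ± 0.12. This argues against it as the whole cause only if adipocytes kept their expression on the diet, which was not tested. Among white adipocyte markers, Retn and Car3 fell while Cd36, Gpd1 and Lipe rose, adjusted over the list alone. Genes of all adipocytes include those of brown fat, so the gap does not tell the kinds of fat apart. Heart muscle as the whole cause stays open. The list mean was 0.52 ± 0.20 with the cardiac covariate and 0.57 ± 0.17 without it. With so few arrays, the covariate fit estimates its error too poorly to decide. High fat replicate 1 and chow replicate 3, the pools lowest in cardiac markers (-1.198 and -1.205), had list means of 0.034 and -0.1. Chow replicate 2, with a cardiac mean of 0.308, had the lowest list mean, -0.454. A response of brown fat or of the vessel wall to the diet was not tested.

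The higher means of macrophage markers could come from more leukocytes of every kind. Class II and lymphocyte genes changed less than macrophage markers by -0.23 ± 0.13, which does not decide, as macrophages make class II genes too. The lymphocyte list had 5 measured members of 21. Of these, Cd37, Cd79a, Coro1a and Ms4a1 had group means of 55.7 to 71.7, near the filter of 40.7, and could show little change. The remaining member, Ighm, had a log2 fold change of 1.04. Its signal was 898.9 in high fat replicate 2, against 224.6 and 263.4 in high fat replicates 1 and 3 and 142 to 276.4 on chow. A single pool as the cause stays open as well. The list mean was -0.071, 0.507 and 0.251 in high fat replicates 1, 2 and 3 and -0.109, -0.453 and -0.125 in chow replicates 1, 2 and 3. Every high fat pool thus lay above every chow pool, replicate 1 by little. Without high fat replicate 2 the mean log2 change was 0.32 ± 0.20 (SE), against 0.46 with all pools, and 21 of 24 members had higher means. The value without that pool lies within 2 SE of 0 although the list passed with the preset correlation (adjusted p = 7.84e-07), and 0 members then passed adjusted over the list alone. With all pools the list had an adjusted p of 0.668 with an estimated correlation. The place of the cells, vessel wall or attached fat, was not tested.

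The higher means of interferon response genes may come from a single pool. Without high fat replicate 3 the mean log2 change was 0.20 ± 0.26 (SE), against 0.55 with all pools, and the list did not pass (adjusted p = 0.179). The full change lies within 2 SE of this value. The full fit includes the pools left and the SE is wide, so this test could hardly have called a single pool and does not decide. The list mean was 0.967 in high fat replicate 3, 0.181 in high fat replicate 2 and -0.327 in high fat replicate 1. The last lay within the range of the chow pools, -0.329 to -0.199. A response to the diet in part of the mice stays open and untested.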
